A study of Homo sapiens with 9 samples.

How the data were processed

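CD4+ T cells of blood donors were enriched from peripheral blood mononuclear cells and sorted by flow cytometry into naive cells (CD45RA high, CCR7 high), central memory cells (CD45RA low, CCR7 high) and effector memory cells (CD45RA low, CCR7 low). Total RNA of each sort was made into a stranded library with an Illumina TruSeq total RNA kit. The series holds 9 libraries in 3 groups, with 3 replicates per group and 1 library per sample.

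The deposited table holds raw read counts per gene, 1 column per library, which the authors made with TopHat2 alignments to genome build hg19 and HTSeq. No version of either tool, no annotation release and no strand setting of the counting is stated, so reads shared by overlapping genes cannot be assigned with certainty. All values are whole numbers, and column totals run from 6613977 to 14435317 reads. Each of the 42628 genes carries an Ensembl identifier and a symbol, and no column was left unused. Symbols are those of the deposited table. Gene types and neighbours came from GENCODE release 29, which is on a later genome build and was joined by Ensembl identifier alone. With it 39702 identifiers matched and 2926 did not. Positions are therefore not given. Long noncoding RNAs (lncRNAs) are genes of the annotation's lincRNA, antisense, sense intronic, sense overlapping, processed transcript and related long noncoding types, 9761 in the table.

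Genes were filtered with filterByExpr of edgeR (minimum count 10), scaled by the trimmed mean of M values (TMM) and fitted with edgeR 4.0.16 in R 4.3.3 as a robust quasi-likelihood model with all 9 libraries in 1 fit. Of the genes, 17410 were tested, 12037 of them protein-coding, 2709 lncRNAs and 647 without a match in the annotation. Each of the 3 pairs of populations was compared with a two-sided quasi-likelihood F-test, and p-values were adjusted by Benjamini and Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. Levels are CPM, counts divided by TMM-adjusted library sizes as edgeR reports them, given as mean ± SD over n = 3 libraries. Standard errors (SE) of log2 fold changes come from the same fit. An average prior count of 2 went into the log2 CPM by which libraries were correlated and checked for overlap. It was not set for the fold changes. Where a group held no read of a gene, the fold is a lower bound, computed with 3 reads over the whole group in place of 0. Where it held 1 to 3 reads, the ratio of the summed reads is given as its 95% exact Poisson interval. Such intervals, and the Wilson intervals of shares, cover counting error only, since reads without molecular identifiers are not independent molecules.

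Fixed before the data were examined were the comparisons, the test, 32 gene lists, the alternatives and the rule for the genes named. The rule took, per comparison, called genes whose 3 and 3 libraries did not overlap. From these it took the 6 protein-coding genes with the highest and the 6 with the lowest fold change (at least 5 CPM in the higher group), and 5 lncRNAs each way (at least 1 CPM). It added the 2 highest and 2 lowest called members of each list, or the most abundant member of a list without a call. CD4, CD3E, PTPRC and CCR7 were always included. Genes of the sex chromosomes that tell donors apart, receptor gene segments and pseudogenes were left out. List members that were not past the test are given as counts, as the rule allowed. Some genes that the rule takes are left out of the text, and counts of calls include them. HLA-DRB1, which the rule also takes, is left out of the text because its reads depend on a donor's alleles.

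The lists cover the naive program, memory surface genes, quiescence, memory transcription factors, Th1, Th2, Th17, regulatory and follicular helper genes, cytotoxic genes and homing receptors. Further lists hold coinhibitory receptors, cytokines, MHC class II, interferon response, cell cycle, glycolysis, the Wnt pathway, immediate-early genes, ribosomal proteins, mitochondrially encoded genes, histones, small nucleolar RNA hosts and lncRNAs described in T cells. The last 8 hold markers of CD8 T cells, gamma-delta T cells, NK cells, B cells, monocytes, dendritic cells, platelets and red cells. Of the listed genes 617 were found and 12 were not, and 28 lists had at least 3 tested members. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Fry's directional p asks whether a list moves on balance 1 way and its mixed p whether members change either way, and neither compares a list with other genes.

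The share of lncRNAs called was set against protein-coding genes matched on mean expression in 20 bins, with 10000 draws. Fold changes of lncRNAs were correlated with those of the gene they are named after (339 pairs) and with the nearest coding gene within 10 kb (2277 pairs). The planned test, 100000 permutations of partners, was run, but its p-values are not printed. They test against a correlation of 0, which other groupings of the libraries do not give, and this was decided after the results were seen. Genes are not independent replicates, and these correlations describe genes and not donors. For the changes shared by both memory populations, 20 simulations drew unchanged memory groups against common naive libraries, without any pairing by replicate number.

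No label says whether replicates of the same number come from the same donor. Correlations between libraries, after group means were removed, were 0.274 to 0.469 for the 9 pairs of the same number and -0.357 to -0.0286 for the 18 pairs of different numbers. The numbers were therefore treated as possible pairs, and values with the replicate number as a block are given beside results that they change. A check for duplicated libraries found none, and all replicates were kept.

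Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 3 libraries, fits of only the compared groups, the replicate block, leaving out each library, and a 2-fold minimum. Added after seeing the data were a fit without small and ribosomal RNA genes, a fit of replicate numbers 2 and 3 alone, and a fit with 1 central memory library, in which the spread comes from the other groups. On simulated data with the spread of these libraries, 75.8%, 80.3% and 74.2% of 4-fold changes were called in the comparisons of central memory with naive, effector memory with naive and effector memory with central memory cells. For 2-fold changes the shares were 26.9%, 28.8% and 34.8%, and false calls made up 12.2%, 3.53% and 6.25% of all calls. Each comparison rests on a single simulated data set with few changed genes. In the first, 17033 of 17253 genes were unchanged and 11 of 90 calls were false. These shares do not carry over to comparisons with far more calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.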

Results

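The data are counts of total RNA, coding and noncoding, in 3 sorted populations of human CD4+ T cells, namely naive, central memory and effector memory cells. Each population has 3 libraries. Naive replicates 1, 2 and 3 held 11811487, 13847529 and 13269961 reads. Central memory replicates held 7511223, 6613977 and 10413963 reads, and effector memory replicates 10546632, 12244634 and 14435317. The study asked how the levels of protein-coding and noncoding genes differ among these populations.

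In RNA level the genes of the sort followed the gates only in part. The gates were set by flow cytometry, and counts per gene do not separate the RA form of CD45. These levels therefore do not test how well the sort worked. CD4, the coreceptor used for enrichment, was at 162 ± 25.7 CPM (SD, n = 3) in naive, 170 ± 12.8 in central memory and 180 ± 17.7 in effector memory cells. It was called in no comparison (adjusted p = 0.797 and 0.558 against naive, 0.991 between the memory populations). Its small log2 difference between central memory and naive cells, 0.07, changed sign with upper-quartile scaling. CCR7, the lymph node homing receptor of the gate, was at 409 ± 36.4 CPM in naive, 193 ± 29.7 in central memory and 117 ± 23.5 in effector memory cells. It was called lower in central memory than in naive cells (adjusted p = 0.00111), although both were gated as CCR7 high. Between the memory populations that the CCR7 gate separates it was not called (0.142), but it was with the replicate block, with DESeq2 and without a filter. There CCR7 was at 173, 179 and 227 CPM in central memory replicates 1, 2 and 3 and at 91.8, 121 and 138 in effector memory replicates. PTPRC, which encodes CD45 and whose RA form defined the gate, was at 2.10e+03 ± 37.6 CPM in naive and 2.89e+03 ± 292 in central memory cells (log2 fold change 0.46, adjusted p = 0.0325). Its call ended with upper-quartile scaling and without naive replicate 1 (adjusted p = 0.0805), naive 2 (0.119), naive 3 (0.118), central memory 2 (0.134) or central memory 3 (0.0613). CD3E, a chain of the CD3 complex, was at 111 ± 21.3, 80.9 ± 7.14 and 78.5 ± 2.67 CPM in naive, central and effector memory cells (adjusted p = 0.0609 and 0.0351 against naive). In central memory cells CD3E was called with the replicate number as a block, with DESeq2, without a filter and with upper-quartile scaling. In effector memory cells PTPRC was called with the block, with DESeq2, with limma-voom and without a filter. The call of CD3E in effector memory cells ended in a fit of only the 2 groups, with replicate numbers 2 and 3 alone, and without naive 1 (0.133), effector memory 1 (0.0937), central memory 2 (0.055), effector memory 2 (0.109) or effector memory 3 (0.0696).

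Central memory libraries also differed in composition. Protein-coding genes took 78.6% ± 4.09 of reads in naive, 69.8% ± 2.99 in central memory and 79.0% ± 2.83 in effector memory libraries (SD, n = 3). RN7SK, a small nuclear RNA that restrains transcription elongation, took 5.64% ± 0.782, 8.14% ± 1.27 and 5.02% ± 1.13 of reads. For both measures the exact permutation test of central memory against naive and against effector memory gave p = 0.1 (two-sided), the smallest that 3 against 3 libraries allow. Mitochondrial ribosomal RNA took 6.93% of reads in central memory replicate 1 (95% Wilson interval 6.92 to 6.95) and 2.78% in replicate 2 (2.77 to 2.80), against 0.138% in replicate 3 and at most 0.424% in a naive library.

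**Figure D1:**
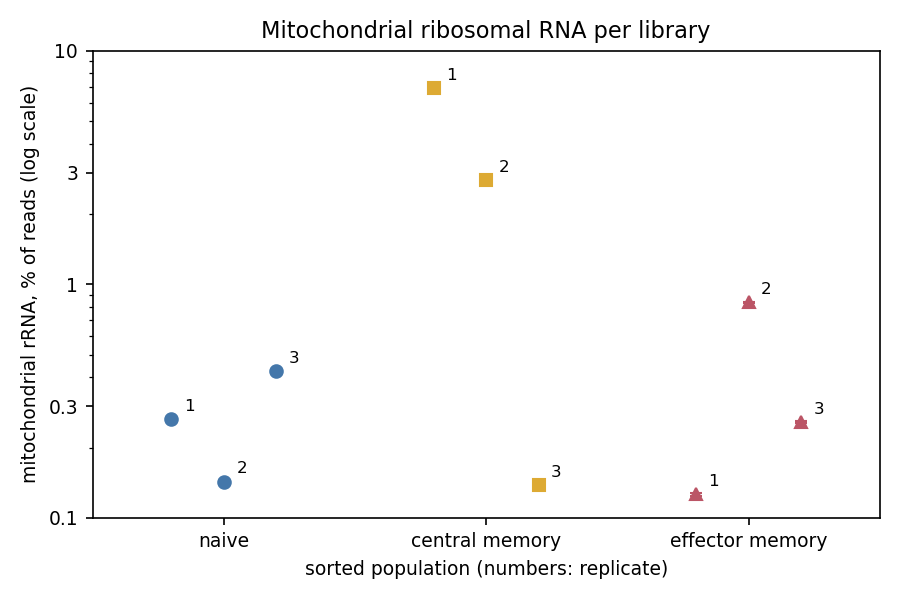
Share of reads from the 2 mitochondrial ribosomal RNA genes (percent, log axis) in each library, with replicate numbers beside the points and 95% Wilson intervals mostly smaller than the points. Central memory replicates 1 and 2, at 6.93% and 2.78%, lie above the highest naive library, at 0.424%.

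Most markers of cells outside the gates were low. CD8A stayed at or under 0.158 CPM and CD8B at or under 0.798 CPM in every population, and TYROBP, an adaptor of NK and myeloid cells, at or under 0.0479 CPM. Of other NK cell markers SPON2 rose from 2.15 CPM in naive to 7.81 CPM in effector memory cells (adjusted p = 0.0261, a call that ended with limma-voom and without naive 1, 2 or 3 or effector memory 2), FCGR3A was at 0 and 2.75 CPM, and KLRF1 at 0.987 and 2.18 CPM. Of the NK cell list only SPON2, KLRF1 and CD247 were tested. CD247 was at 199, 148 and 167 CPM in naive, central and effector memory cells, so it does not single out NK cells here. The monocyte gene LYZ was at 0.952, 1.88 and 2.51 CPM in naive, central and effector memory cells. LYZ was not past the test against naive (adjusted p = 0.245 and 0.0715). No marker of monocytes, dendritic cells, platelets or red cells was called. With the block LYZ was called higher and the dendritic marker IL3RA lower in effector memory cells, and the platelet marker GP1BA lower in both memory populations. The gamma-delta receptor genes TRGC1 and TRGC2 were at 3.18 and 2.72 CPM in naive, 5.02 and 5.97 in central memory and 10.4 and 14.9 in effector memory cells, and TRDC at 2.66, 2.75 and 3.28 CPM. TRGC2 varied widely, at 1.55, 26.2 and 16.8 CPM in effector memory 1, 2 and 3 and 0.677, 2.60 and 4.90 CPM in naive 1, 2 and 3. MS4A1, which encodes the B cell antigen CD20, had no read in the naive libraries and 2.36 ± 0.787 CPM in effector memory cells (at least 33.9-fold higher, adjusted p = 0.000732), while PAX5 and IGKC, abundant in B cells, had no read in any library.

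The comparison of central memory with naive cells asks what separates antigen-experienced cells that kept CCR7 from cells that have not met antigen. CCR4 (ENSG00000183813), a chemokine receptor that guides cells to skin, was at 254 ± 19.0 CPM in central memory and 3.66 ± 0.464 CPM in naive cells (SD, n = 3), a log2 fold change of 6.11 (SE 0.19, adjusted p = 1.97e-09). KLRB1 (ENSG00000111796), the lectin-like receptor CD161, was at 172 ± 19.7 against 3.85 ± 1.41 CPM, and MAF (ENSG00000178573), a transcription factor of helper cells, at 200 ± 22.7 against 9.99 ± 6.73 CPM. PTPN13, a tyrosine phosphatase, rose from 0.147 ± 0.133 to 23.0 ± 1.09 CPM, a log2 fold change of 7.22. In the other direction BACH2 (ENSG00000112182), a repressor that restrains effector differentiation, fell by 1.75 on the log2 scale, from 134 ± 11.6 to 39.8 ± 2.60 CPM, and CCR7 fell by 1.08 (SE 0.16, adjusted p = 0.00111).

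Among the genes with the largest rises were CCR6, a receptor of Th17 and mucosal cells, at 10.4 ± 2.34 CPM and 62.3 to 1.89e+03-fold above its 2 naive reads. LGALS3, a galectin, and HLA-DRA, an MHC class II chain, had no read in naive libraries and were at least 56.9-fold and at least 36.0-fold higher. Among the lowest, the transcription factor SOX4 fell by 3.46 on the log2 scale, from 15.5 ± 5.87 to 1.30 ± 0.981 CPM, and the cytoskeletal gene ADD2 fell by 3.54, from 24.0 ± 4.20 to 1.98 ± 1.59 CPM. In all, 1739 of 17410 genes were called, 1172 higher and 567 lower in central memory cells, and 883 of them changed at least 2-fold. Of the called genes, 1722 had no overlap between the 3 and 3 libraries, as had 31.3% of all genes tested, against 10% by chance.

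With upper-quartile scaling the split was 915 higher and 739 lower, so the excess of rises depends on the scaling. With the replicate number as a block 4540 genes were called (2686 higher, 1854 lower), 1728 of the 1739 among them. The count fell to 1154, 933 and 967 without naive replicates 1, 2 and 3 and to 902 without central memory replicate 2.

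By list, 14 of 20 memory surface genes rose, none fell and 6 were not past the test (16 rose adjusted over the list alone; camera's adjusted p = 6.90e-19). Of the 20 genes of the naive program 11 fell, BACH2 and the costimulatory receptor gene TMIGD2 (fell by 2.15) most, and 1 rose (14 fell and 1 rose adjusted over the list alone; adjusted p = 1.07e-09). The gene that rose is CD28, the costimulatory receptor that memory cells also carry, at 478 ± 12.1 against 289 ± 25.3 CPM. Of 11 Th17 genes 8 rose, with CCR6 and the interleukin receptor IL23R (at least 20.2-fold) highest, and ABCB1, a drug efflux pump, fell by 1.14 (9 and 1 adjusted over the list alone; adjusted p = 5.74e-08). Of 26 homing receptors 12 rose and the integrin ITGA6 fell by 0.84, from 680 ± 80.9 to 381 ± 46.5 CPM (13 and 1 adjusted over the list alone; adjusted p = 1.19e-06). Of 17 memory transcription factors 9 rose (10 rose and 1 fell adjusted over the list alone). Of 10 regulatory T cell genes 7 rose, among them TIGIT, an inhibitory receptor, at 52.1 ± 11.5 against 4.20 ± 1.42 CPM (7 adjusted over the list alone). Of 12 follicular helper genes 5 rose (8 adjusted over the list alone). Of 25 Wnt pathway genes 8 fell, the corepressor TLE2 by 1.32, and the cyclin CCND2 rose (10 and 1 adjusted over the list alone). These lists and the lncRNAs described in T cells kept their call with an estimated correlation (adjusted p = 0.0222 to 0.038). With both the block and an estimated correlation, 5 of them had an adjusted p of 0.064, namely the memory transcription factors, regulatory, follicular helper, Wnt and lncRNA lists.

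Other lists passed camera with the preset correlation only. Of 12 Th1 genes 7 rose, among them IL18RAP, a chain of the receptor for interleukin 18, by 3.29 on the log2 scale and named after its values were seen (8 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation). Of 7 Th2 genes 4 rose, CCR4 and CCR8 most, and the interleukin receptor IL4R fell by 0.94 (4 and 1 adjusted over the list alone; adjusted p = 0.078 with an estimated correlation). Of 21 cell cycle genes 10 rose, among them the topoisomerase TOP2A, at 18.7 ± 15.1 against 0.551 ± 0.199 CPM (14 adjusted over the list alone and 16 with the block; adjusted p = 0.337 with an estimated correlation). Replicate 1 stood apart, with TOP2A at 36.1 CPM against 9.77 and 10.3 in the other central memory libraries. MKI67 was at 31.5 CPM there, against 3.54 and 6.98 in the others. The call of MKI67 ended without naive 1 (adjusted p = 0.0991), naive 2 (0.0896) or naive 3 (0.118). Of 81 ribosomal protein genes 14 fell (24 adjusted over the list alone, 36 with the block; adjusted p = 0.394 with an estimated correlation). Of 13 mitochondrially encoded genes 2 fell (3 adjusted over the list alone, 7 with the block; adjusted p = 0.407 with an estimated correlation). Mitochondrial mRNAs together took 0.531% of reads in naive replicate 1, 0.208% and 0.250% in naive 2 and 3 and 0.158% to 0.217% in memory libraries. Much of the fall in that summed share therefore lies in naive replicate 1. Camera's call of the list with the preset correlation was kept in 9 of 9 fits that left out a library. Of 17 immediate-early genes 4 rose and 1 fell, IER5 among the rises (8 and 1 adjusted over the list alone, 9 and 1 with the block; adjusted p = 0.358 with an estimated correlation). Of 28 histone genes 4 rose, HIST1H4J from 30.6 ± 3.60 to 103 ± 25.5 CPM (4 adjusted over the list alone, 9 with the block; adjusted p = 0.47). Of 12 cytokine genes 4 rose, with IL2 at least 22.7-fold higher (5 adjusted over the list alone, 7 higher and 1 lower with the block; adjusted p = 0.396). Of 23 interferon response genes 3 rose, OAS1 among them (3 adjusted over the list alone, 11 higher and 1 lower with the block; adjusted p = 0.553 with an estimated correlation). Camera's own call of that list, adjusted p = 0.0372, ended without central memory 1 (0.276), naive 2 (0.0513), central memory 2 (0.0731) or naive 3 (0.173). No list call was made for cytotoxic genes (4 rose and the protease CTSW fell by 1.24, of 14), coinhibitory receptors (4 rose and 1 fell, of 13), MHC class II (1 of 9 rose), glycolysis (2 rose and 1 fell, of 21), small nucleolar RNA hosts (1 of 19 rose), quiescence (0 of 15 called) or the markers of gamma-delta T cells, NK cells, B cells and monocytes. With the block 6 rose and 2 fell of the cytotoxic genes, 5 and 3 of the coinhibitory receptors, 4 and 1 of MHC class II, 6 and 2 of glycolysis, 3 and 1 of the small nucleolar RNA hosts and 3 and 3 of quiescence.

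**Figure D2:**
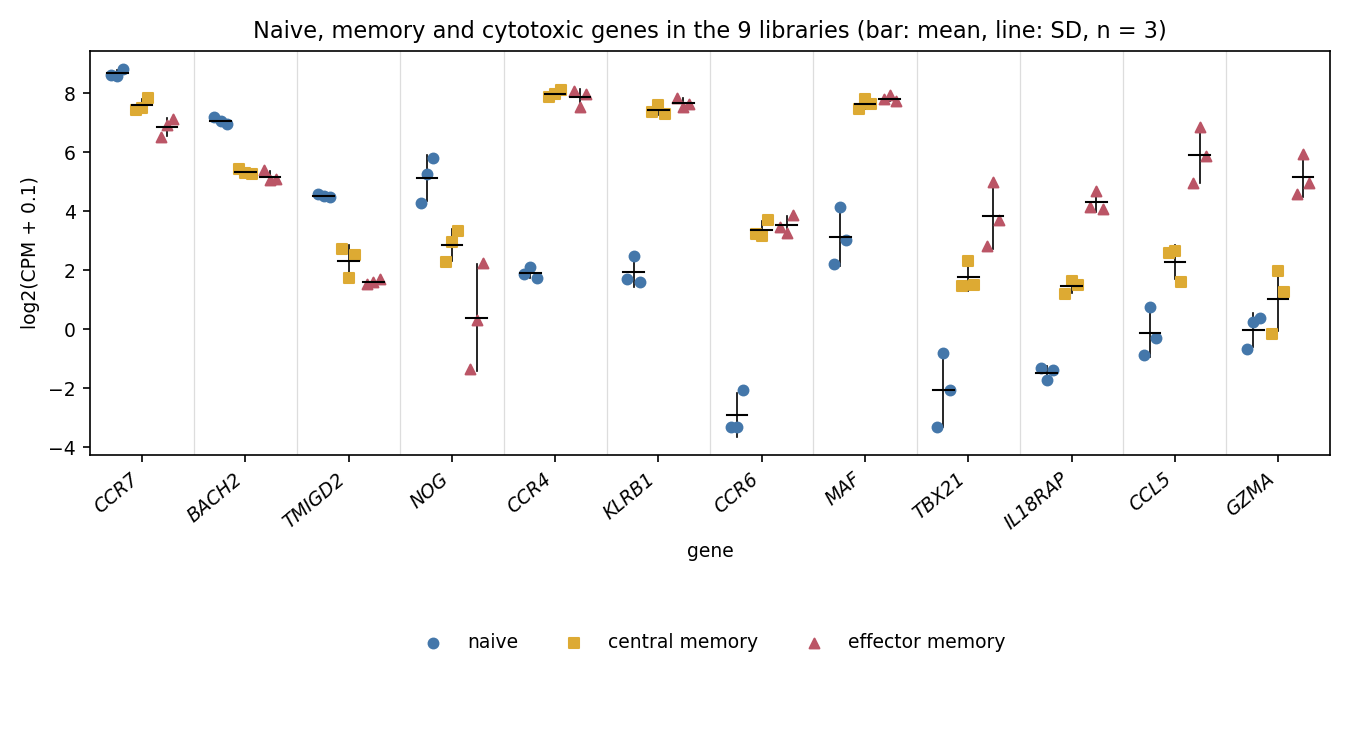
Levels of 12 genes, as log2 of CPM plus 0.1, in the 3 libraries of each population (points), with the mean (bar) and SD (line) of the log values. CCR4, KLRB1, CCR6 and MAF lie higher in all central and effector memory libraries than in any naive library, and IL18RAP, CCL5 and GZMA are highest in effector memory libraries.

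LncRNAs changed in both directions. LINC00892 (ENSG00000233093), which lies beside the CD40 ligand gene, was at 10.7 ± 4.06 CPM in central memory and 0.412 ± 0.241 CPM in naive cells, a log2 fold change of 4.68 (SE 0.41, adjusted p = 2.55e-05). IL21-AS1, antisense to the cytokine gene IL21, was at 2.87 ± 0.916 CPM and 21.3 to 4.94e+03-fold above its 1 naive read, and AC106801.1, RP11-106M7.1 and RP11-428L9.2 rose from at most 3 naive reads each. LEF1-AS1 (ENSG00000232021), antisense to the gene of the naive cell transcription factor LEF1, fell by 2.03 (SE 0.20, adjusted p = 5.57e-05), from 38.2 ± 4.85 to 9.34 ± 0.852 CPM, and CASC15 fell by 3.63, from 5.38 ± 2.68 to 0.465 ± 0.345 CPM. LINC00563 was at 1.86 ± 0.395 CPM in naive cells, had no read in central memory libraries and was at least 13.7-fold lower.

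Of 2709 lncRNAs tested 166 were called, 114 higher and 52 lower (118 adjusted over the tested lncRNAs alone). Of these 47 higher and 21 lower were antisense and 46 and 24 lincRNA genes. Of 38 lncRNAs described in T cells or as nuclear lncRNAs 16 rose and 3 fell (20 and 4 adjusted over the list alone; adjusted p = 3.64e-05 by camera). The share of lncRNAs called, 6.13%, was lower by 3.18 percentage points than the 9.31% (95% of draws 8.23 to 10.4) of coding genes of matched expression. The difference was -1.80 points without naive replicate 1, -2.05 without naive 3 and -5.72 with the block. With the block 425 lncRNAs were called (231 higher, 194 lower). The count fell to 79 without naive replicate 2, 83 without naive 3 and 88 without central memory 2.

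The comparison of effector memory with naive cells asks what marks antigen-experienced cells that lost CCR7. CCL5 (ENSG00000161570), a chemokine stored in cytotoxic granules, was at 68.8 ± 43.7 CPM in effector memory and 0.911 ± 0.587 CPM in naive cells (SD, n = 3), a log2 fold change of 6.2 (SE 0.65, adjusted p = 0.000329). TBX21 (ENSG00000073861), the master transcription factor of Th1 cells, was at 17.2 ± 13.1 against 0.207 ± 0.246 CPM, and CCR4 and KLRB1 stood at 235 ± 46.0 and 205 ± 23.3 CPM, much as in central memory cells. CCR7 fell by 1.80 (SE 0.16, adjusted p = 1.35e-05), and NOG (ENSG00000183691), an inhibitor of bone morphogenetic proteins, fell by 4.12, from 37.9 ± 18.5 to 2.02 ± 2.30 CPM.

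Genes without a read in naive libraries included JAKMIP1, a microtubule-associated gene of effector cells (at least 165-fold higher), HLA-DRA (at least 153-fold), NHSL2 (at least 138-fold), LGALS3 (at least 125-fold) and the receptor kinase LTK (at least 95.1-fold). Among the lowest, DACT1, a regulator of Wnt signals, fell by 5.02 on the log2 scale, from 32.9 ± 27.9 to 1.02 ± 0.539 CPM, and the chromatin remodeller SMARCA1 fell by 4.33. CACHD1, a calcium channel modulator, fell by 5.56. In all, 2046 genes were called, 1342 higher and 704 lower in effector memory cells, and 1228 changed at least 2-fold. Of these 2036 had no overlap between the libraries, as had 33.1% of all genes tested, against 10% by chance. With upper-quartile scaling the split was 1171 higher and 943 lower, and with the replicate block 4631 genes were called (2629 higher, 2002 lower), 2045 of the 2046 among them. Without naive replicate 3 the count was 1363.

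By list, 17 of 20 memory surface genes rose and none fell (19 adjusted over the list alone; camera's adjusted p = 1.54e-22). Of the naive program 15 of 20 fell, NOG and AIF1 (fell by 3.10) most, while CD28 rose by 0.54 (16 fell and 1 rose adjusted over the list alone; adjusted p = 1.18e-15). Of 17 memory transcription factors 13 rose, TBX21 among the highest (14 adjusted over the list alone; adjusted p = 5.17e-12). Of 12 Th1 genes 10 rose (10 adjusted over the list alone; adjusted p = 1.83e-08). Of 11 Th17 genes 9 rose (10 adjusted over the list alone; adjusted p = 1.79e-12). Of 7 Th2 genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 7.43e-06). Of 10 regulatory T cell genes 7 rose, the costimulatory receptor gene TNFRSF18 at least 45.5-fold (8 adjusted over the list alone). Of 12 follicular helper genes 5 rose, the transcription factor gene TOX from 3.17 ± 1.15 to 19.5 ± 3.69 CPM and the inhibitory receptor gene PDCD1 from 0.189 ± 0.147 to 5.85 ± 2.61 CPM (7 adjusted over the list alone). Of 26 homing receptors 15 rose and ITGA6 fell by 1.06 (16 and 1 adjusted over the list alone). Of 25 Wnt genes 7 fell, the receptor LRP6 and the inhibitor NKD1 by 1.84 and 2.21, and CCND2 rose (9 and 2 adjusted over the list alone). These lists and the T cell lncRNAs kept their call with an estimated correlation (adjusted p = 0.00848 to 0.0365). With both the block and an estimated correlation the Th2 (adjusted p = 0.0643), follicular helper (0.0639), Wnt (0.0643) and lncRNA (0.0828) lists did not.

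Cytotoxic genes rose in 9 of 14 cases with none lower (12 adjusted over the list alone; camera's adjusted p = 7.62e-07, but 0.14 with an estimated correlation and 0.0381 with the block as well). CCL5 kept its call without each library in turn. The granule genes NKG7 and GZMH, with the highest fitted changes, varied widely among effector memory libraries, at 20.4 ± 21.4 and 19.9 ± 24.7 CPM. Replicate 2 stood apart, at 44.7 and 48.1 CPM, against 4.08 and 2.23 in replicate 1 and 12.4 and 9.26 in replicate 3. CCL5, GZMA and TBX21 were also highest in replicate 2, and HOPX was not. The calls of NKG7 and GZMH ended by limma-voom and without a filter, without naive replicate 1 (adjusted p = 0.127 and 0.0864), naive 2 (0.183 and 0.064) or naive 3 (0.156 and 0.104), for NKG7 without effector memory 3 (0.0696) and for GZMH without central memory 3 (0.0804). Of 9 MHC class II genes 5 rose (7 adjusted over the list alone; adjusted p = 0.058 with an estimated correlation). Of 12 cytokine genes 6 rose (8 adjusted over the list alone). Of 21 glycolysis genes 5 rose, the phosphofructokinase gene PFKP among them (5 adjusted over the list alone, 9 higher and 1 lower with the block). Of 17 immediate-early genes 9 rose, FOS from 18.1 ± 8.86 to 65.6 ± 15.9 CPM (11 rose and 1 fell adjusted over the list alone). For these 3 lists the adjusted p was 0.114 with an estimated correlation. Of 21 cell cycle genes 9 rose, the spindle gene TPX2 among them (12 adjusted over the list alone, 15 with the block), with TPX2 at 7.97 CPM in effector memory replicate 1 against 2.75 and 2.47 in the others. Of 28 histone genes 5 rose (5 adjusted over the list alone, 14 with the block). Of 81 ribosomal protein genes 10 fell and 1 rose (26 and 1 adjusted over the list alone, 42 and 3 with the block). Of 13 mitochondrially encoded genes 4 fell (9 adjusted over the list alone, 10 with the block). Again naive replicate 1 had 0.531% of reads in mitochondrial mRNAs, above 0.208% and 0.250% in the other naive libraries. Camera's call of that list with the preset correlation was kept in 9 of 9 fits that left out a library. For these 4 lists the adjusted p was 0.28 with an estimated correlation.

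The remaining calls of camera were weaker. Of 13 coinhibitory receptors 4 rose and 1 fell (4 and 1 adjusted over the list alone, 7 and 2 with the block; camera's adjusted p = 0.0369, 0.309 with an estimated correlation). That call ended without naive 1 (0.0667), effector memory 2 (0.0701) or effector memory 3 (0.0671). Of 23 interferon response genes 3 rose, OAS1 from 5.72 ± 0.0652 to 18.0 ± 1.19 CPM and OASL from 1.11 ± 0.166 to 7.67 ± 4.21 CPM (4 adjusted over the list alone, 11 with the block; adjusted p = 0.36 with an estimated correlation, and 0.0527 by camera without effector memory 1). The B cell list, of which MS4A1 alone was called among 3, had camera's adjusted p of 0.0485, 0.28 with an estimated correlation and 0.0727 with the block, and its call also ended without central memory 3 (0.0525) or effector memory 3 (0.0671). Of 15 quiescence genes 2 fell, the transcription factor FOXO1 from 213 ± 13.5 to 133 ± 8.69 CPM among them, without a list call. That list's median and mean were above 0 while camera's direction was down. The lists of small nucleolar RNA hosts (1 of 19 fell), NK cells (1 of 3 rose), monocytes and gamma-delta T cells were not called, the last until the block was used (adjusted p = 0.013, and 0.0996 with the block and an estimated correlation). With the block 3 quiescence genes rose and 3 fell, 3 small nucleolar RNA hosts rose and 4 fell, and 2 gamma-delta genes rose.

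**Figure D3:**
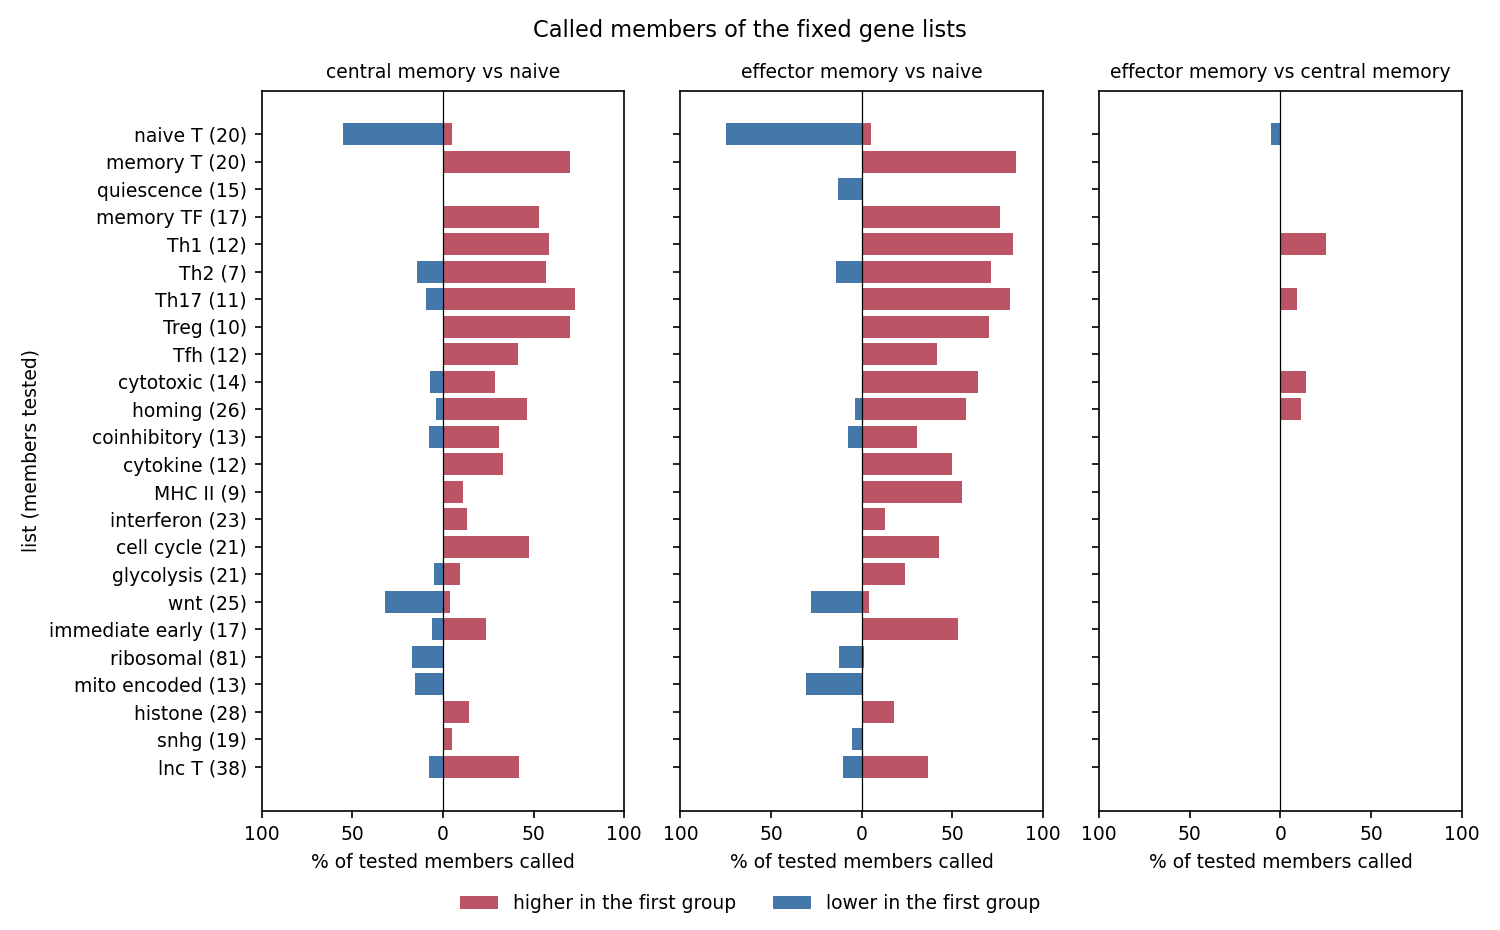
Percent of the tested members of each fixed list that were called higher (right) or lower (left) in the first group of each comparison, with the number tested in parentheses. Memory surface genes rose in 14 and 17 of 20 cases against naive cells, and few members were called between effector and central memory cells.

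LncRNAs of effector memory cells included LINC00299 (ENSG00000236790), at 3.87 ± 1.12 CPM with no naive read (at least 53.2-fold higher, adjusted p = 0.000788), RP11-383H13.1 (at least 36.8-fold), AC007278.2 (at least 31.7-fold), and LINC00892, which rose from 0.412 ± 0.241 to 14.8 ± 0.836 CPM. LEF1-AS1 fell by 2.95 (SE 0.21, adjusted p = 2.36e-06), from 38.2 ± 4.85 to 4.88 ± 1.21 CPM, RP11-641A6.2 by 3.18, from 22.2 ± 7.45 to 2.39 ± 1.07 CPM, CASC15 by 3.59. C14orf64 fell by 1.36. LINC00478 had 1 effector memory read and was 13.6 to 3.11e+03-fold lower. Of 2709 lncRNAs 203 were called, 110 higher and 93 lower (164 adjusted over the tested lncRNAs alone). Of these 38 and 37 were antisense and 52 and 41 lincRNA genes. Of the 38 lncRNAs described in T cells or as nuclear lncRNAs 14 rose and 4 fell (18 and 5 adjusted over the list alone; adjusted p = 0.000794 by camera). The share called, 7.49%, was lower by 6.61 percentage points than the 14.1% (95% of draws 12.8 to 15.4) of matched coding genes. The difference was -4.24 points without naive replicate 1, -3.68 without naive 2, -4.11 without naive 3 and -8.78 with the block. With the block 481 lncRNAs were called, 205 higher and 276 lower, and with upper-quartile scaling 103 rose and 124 fell, so which side is larger depends on the analysis. Without a filter 312 were called, without effector memory 2 124 and without naive 3 132.

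**Figure D4:**
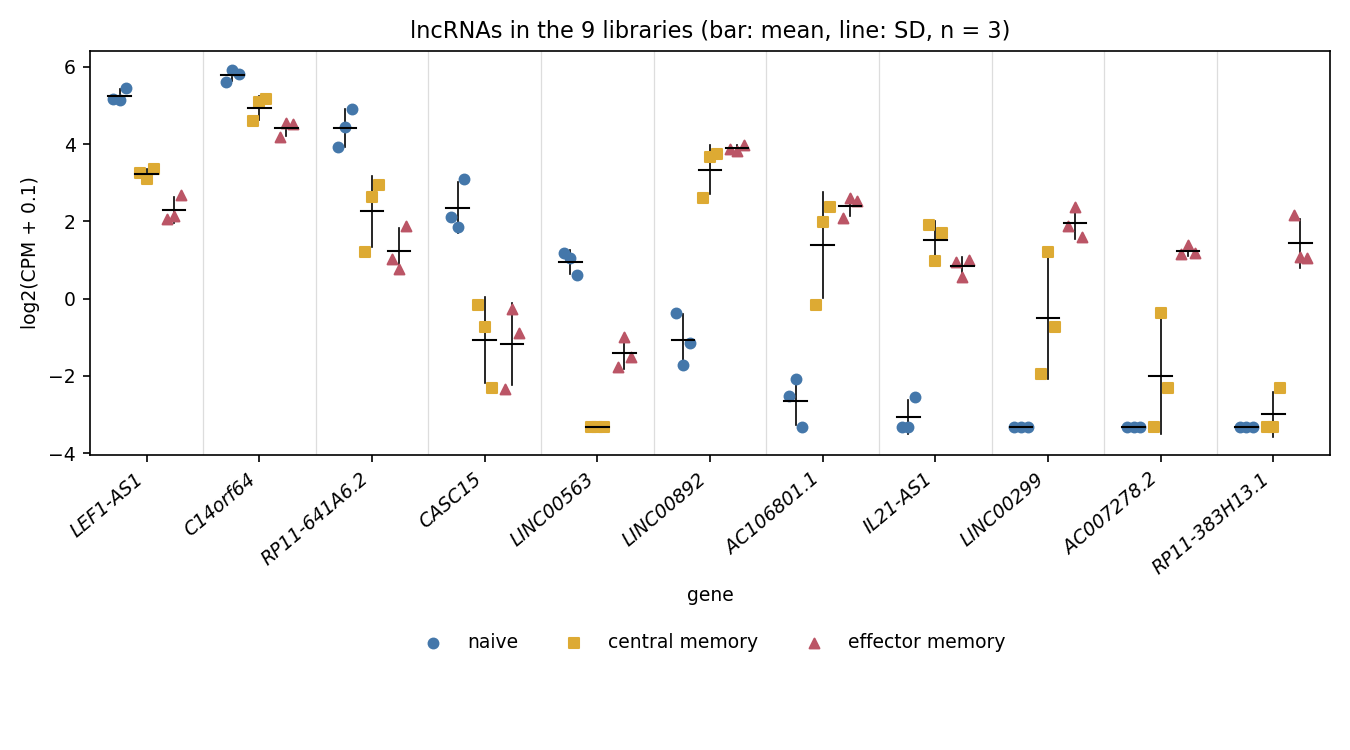
Levels of 11 lncRNAs, as log2 of CPM plus 0.1, in the 3 libraries of each population (points), with the mean (bar) and SD (line) of the log values; the lowest points are libraries without a read. LEF1-AS1 lies higher in each naive library than in any memory library, and LINC00299, AC007278.2 and RP11-383H13.1 have no read in naive libraries.

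The comparison of effector with central memory cells asks what separates the memory populations by CCR7. IL18RAP (ENSG00000115607), a chain of the receptor for interleukin 18, was at 20 ± 4.83 CPM in effector and 2.66 ± 0.418 CPM in central memory cells (SD, n = 3), a log2 fold change of 2.91 (SE 0.27, adjusted p = 0.00138). GZMA (ENSG00000145649), a granule protease, was at 38.6 ± 19.5 against 2.33 ± 1.54 CPM, and PLEK, a platelet and leukocyte signalling gene, at 33.0 ± 22.6 against 1.92 ± 0.735 CPM. ITGAM, an integrin chain, HOPX, a cofactor of effector cells, RASGEF1A and ABCB1 were higher by 4.07, 2.92, 2.86 and 1.84 on the log2 scale. ADTRP (ENSG00000111863), a regulator of a coagulation inhibitor, fell by 1.41 (SE 0.16, adjusted p = 0.00571), from 48.3 ± 7.78 to 18.1 ± 1.54 CPM, and FHIT, a member of the naive program, by 1.27, the growth factor receptor IGF1R by 1.04 and the transcription factor PLAG1 by 0.87.

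In all, 17 genes were called, 13 higher and 4 lower in effector memory cells, every one without overlap between the libraries, as had 10.6% of all genes tested, against 10% by chance. Outside the rule for named genes PTPN13, B4GALT5, CXCR6 and ERN1 were higher, and they are named after their values were seen. At an unadjusted p under 0.05 there were 1059 genes, and 41 coding genes passed when adjusted over the tested coding genes alone. With the replicate block 428 genes were called (286 higher, 142 lower), the 17 among them, and with DESeq2 144. Without a filter 250 were called, with only the 2 groups 35, without small and ribosomal RNA genes 27, and with replicate numbers 2 and 3 alone 36. Limma-voom called 11 of the 17 and ended the calls of PLEK, ITGAM, GZMA, HOPX, RASGEF1A and PLAG1, the last also ended by the fit of only the 2 groups. Of the 12 calls that the rule takes only those of IL18RAP and ADTRP held without each library in turn. Without central memory 3, 2 genes were called and the other 10 of these ended (adjusted p = 0.0663 to 0.185). Without central memory 2 the count was 3 and 9 calls ended (0.0632 to 0.244). Without effector memory 2 it was 11 and 6 ended (0.0646 to 0.234). Another 6 calls ended without central memory 1 (0.0533 to 0.139), 4 without effector memory 3 (0.0727 to 0.175) and 2 without effector memory 1 (0.053 to 0.0539). The count rose to 32, 27 and 31 without naive replicates 1, 2 and 3 and to 32 without effector memory 1.

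Between the memory populations 8 lists kept camera's call with an estimated correlation. With the preset correlation camera also called 3 to 15 lists in the 9 other splits of these 6 libraries, where edgeR called 0 genes, so its number of lists carries little weight alone. Of 14 cytotoxic genes 2 were called higher, GZMA and HOPX, but 12 adjusted over the list alone and 11 with the block (camera's adjusted p = 1.84e-18, 0.0388 with an estimated correlation). Of 17 memory transcription factors 0 were called by edgeR, 10 rose adjusted over the list alone and 9 with the block (adjusted p = 2.42e-12, 0.0137 with an estimated correlation). Of 9 MHC class II genes likewise 0 were called, 6 rose adjusted over the list alone and 7 with the block (adjusted p = 5.56e-12, 0.0232 with an estimated correlation). Of 12 Th1 genes 3 rose, IL18RAP and CXCR6 among them (5 adjusted over the list alone, 6 with the block; adjusted p = 0.0312 with an estimated correlation). Of 11 Th17 genes ABCB1 alone rose (3 adjusted over the list alone, 3 with the block; 0.0232). Of 26 homing receptors 3 rose (4 adjusted over the list alone, 5 higher and 1 lower with the block; 0.0255). Of 20 memory surface genes 0 were called, 4 adjusted over the list alone and 7 with the block (0.0388). Of the 20 genes of the naive program FHIT alone fell, 10 fell adjusted over the list alone and 11 with the block (adjusted p = 7.19e-16, 0.0156 with an estimated correlation). CCR7 itself, lower by 0.72 on average, had an adjusted p of 0.142 and was called with the block, with DESeq2 and without a filter.

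A further 10 lists passed camera, and lost that call with an estimated correlation, without a gene called by edgeR over all genes. These were Th2 genes (adjusted p = 0.25), regulatory T cell genes (0.166), coinhibitory receptors (0.283), cytokines (0.166), glycolysis (0.166), immediate-early genes (0.25), NK cell (0.186) and B cell markers (0.186), all upward, and the cell cycle (0.7) and small nucleolar RNA hosts (0.357), both downward. With the block at most 3 members of any of these lists were called. With both the block and an estimated correlation cytokines passed (0.0216). Calls of the preset test that ended without 1 library were those of B cell markers (without naive 1, 2 or 3, adjusted p = 0.113, 0.11 and 0.107, central memory 1, 0.244, central memory 2, 0.229, or effector memory 3, 0.302) and NK cell markers (without effector memory 2, 0.106, or 3, 0.15). Those of coinhibitory receptors, cell cycle and small nucleolar RNA hosts ended without central memory 1 (0.357, 0.656 and 0.476), effector memory 2 (0.085, 0.267 and 0.186) or effector memory 3 (0.098, 0.624 and 0.15), the last list also without central memory 2 (0.101). The call of Th2 genes ended without central memory 3 (0.0526) or effector memory 3 (0.15), that of immediate-early genes without central memory 3 (0.0526) and that of regulatory genes without effector memory 3 (0.065). Lists of quiescence, follicular helper, interferon, Wnt, ribosomal, mitochondrial, histone, T cell lncRNA, monocyte and gamma-delta T cell genes were not called, the last until the block was used (0.00154, and 0.0737 with the block and an estimated correlation). Median, mean and camera's direction differed in sign for the quiescence, Wnt, ribosomal protein and T cell lncRNA lists.

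No lncRNA was called between effector and central memory cells by edgeR or by limma-voom, while 128 had an unadjusted p under 0.05 and DESeq2 called 10. With the replicate block 28 were called, 12 higher and 16 lower. Of these 4 are named here, chosen after their values were seen. They are RP11-383H13.1, at 2.79 ± 1.37 CPM in effector memory cells with 1 read in central memory libraries, LINC00963, at 28.5 ± 2.5 against 14.2 ± 2.82 CPM, LEF1-AS1, at 4.88 ± 1.21 against 9.34 ± 0.852 CPM, and CHRM3-AS2, at 99.4 ± 6.15 against 144 ± 17.8 CPM. Without a filter 19 were called, and 1 was called with only the 2 groups, without small and ribosomal RNA genes, and without naive replicate 1, 2 or 3.

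Both memory populations differed from naive cells largely in common genes. CCR4, KLRB1, MAF, CCR6, LINC00892 and CD28 were higher and CCR7, ITGA6, LEF1-AS1, ADD2 and CASC15 lower in both. The genes called in the same direction in both comparisons were 1271, of which 917 rose and 354 fell, and no gene was called in opposite directions. Independent lists of these sizes would share 113. Simulated unchanged groups against common naive libraries shared at most 1. With no changed gene few calls are expected there, so that number cannot gauge what shared controls add. The correlation of the fold changes across genes was 0.863, against 0.474 in the simulations, and their covariance was 0.724 against 0.0786, a difference of 0.646. Because the 3 naive libraries serve both comparisons and cannot be divided into parts of 2 or more, some of the excess over independent lists may come from shared controls. With the block 3208 genes were shared, and the count was 782 without naive replicate 2, 785 without naive 3 and 823 without central memory 2.

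**Figure D5:**
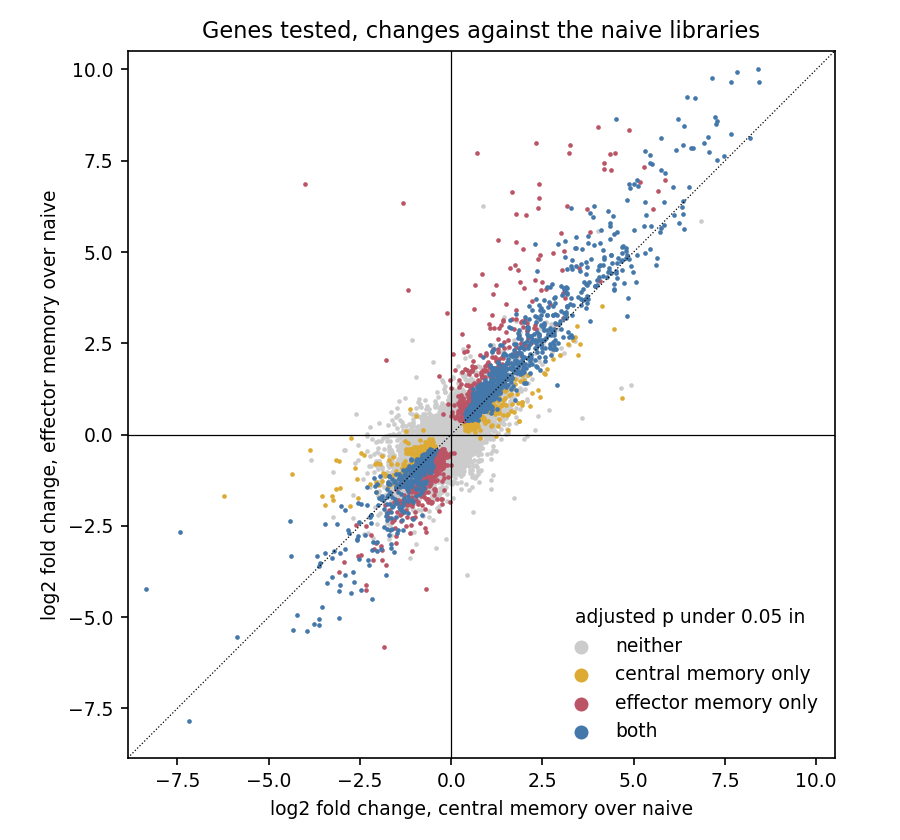
Log2 fold change of each tested gene in central memory (x axis) and effector memory cells (y axis) over naive cells, coloured by the comparisons with an adjusted p under 0.05; the dotted line marks equal changes. The 1271 genes called in both lie in the quadrants of equal direction, and the correlation across genes is 0.863.

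CCR7 and LEF1-AS1 descended, and IL18RAP ascended, from naive through central memory to effector memory cells. Of the 2046 genes called between effector memory and naive cells, 1593 (77.9%) had their central memory level between the others. These were 1032 of 1342 rises and 561 of 704 falls. For 3 equal groups chance gives 33.4% over all differences and 82.5% among the most extreme. The 82.5% comes from a smaller and more extreme share of differences than the 11.8% of genes called here. The 77.9% can therefore not be placed above or below chance. Genes called both from naive to central memory and from central to effector memory in the same direction numbered 10, of which 7 rose and 3 fell. With the block there were 220 (160 and 60), and 3094 genes lay between.

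Some lncRNAs changed together with the coding genes they are named after. LEF1-AS1 and LEF1 fell by 2.03 and 0.69 in central memory and by 2.95 and 1.28 in effector memory cells, and IFNG-AS1 and IFNG, the gene of interferon gamma, rose by 2.46 and 3.67 and by 3.26 and 3.72 (pairs chosen after their values were seen). The adjusted p of IFNG-AS1 and IFNG was 0.022 and 0.00559 in central and 0.00281 and 0.00297 in effector memory cells, and the call of IFNG in central memory cells ended with limma-voom and with replicate numbers 2 and 3 alone. Across 339 pairs Spearman's correlation of the fold changes was 0.419 for central memory with naive, 0.516 for effector memory with naive and 0.175 for effector with central memory cells, and Pearson's r was 0.497, 0.595 and 0.156. The planned permutation p-values are left out, because they test against 0 and other groupings of the libraries do not give 0. In 99 other groupings of the 9 libraries, made for the second comparison only, Spearman's correlation ran from 0.0829 to 0.512 with a median of 0.247. Among them are the real 3 groups under exchanged names, at 0.419, and some groupings that give identical correlations. Where both partners were called they had the same direction in 10 of 10 and 12 of 12 pairs. For the nearest coding gene within 10 kb, 2277 pairs gave Spearman's correlation of 0.420, 0.506 and 0.204. The lowest of these correlations, 0.175, was 0.0948 without central memory replicate 3 and 0.0927 without effector memory replicate 3. Most neighbours overlap, and the strand setting of the counting is not known, so a read of 1 gene may have been counted for the other. Such shared reads can raise the correlation.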

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

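The tests in this part were chosen after the result was seen. Mitochondrial ribosomal RNA, the product of MT-RNR1 and MT-RNR2, took 6.93% of reads in central memory replicate 1 (95% Wilson interval 6.92 to 6.95), 2.78% in central memory replicate 2 (2.77 to 2.80) and 0.839% in effector memory replicate 2 (0.834 to 0.844). These lie above the highest naive library, 0.424%, while central memory replicate 3 was at 0.138%. As central memory replicate 3 does not share it, this is a feature of single libraries and not shown for the population. A permutation test of 3 against 3 libraries cannot give a p under 0.1 and so decides nothing here.

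If central memory cells held more mitochondrial RNA, the mitochondrial mRNAs should rise with the ribosomal RNA, whose mean share was higher by 3.57 on the log2 scale than in naive cells. The 13 mRNAs changed by a median of -0.57 (SD 0.152). Part of that fall lies in naive replicate 1, at 0.531% of reads, but the mRNAs took 0.158% to 0.209% in central memory libraries and 0.208% in the lowest naive library, so no rise like that of the ribosomal RNA is seen without it either, which argues against that explanation. The ribosomal RNA may instead have escaped removal during library preparation. Other ribosomal RNA genes reached at most 0.337 CPM in any library, a level too low, in a table that may not count such repeats, to decide on this. CTD-2328D6.1, a gene absent from the annotation used here, took 2.81%, 1.09% and 0.383% of reads in the same 3 libraries.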

How the results depend on the processing

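The settings of this part were planned before the data were seen, except 3 fits chosen afterwards, namely those without small and ribosomal RNA genes, with replicate numbers 2 and 3 alone and with 1 central memory library. The splits of libraries were also chosen after the result was seen. With 1 central memory library that group has no spread of its own and the test borrows it from the other groups, so a fall in calls there says little. For no other result was the cause of a change tested, and depth differs between populations, with the fewest reads in central memory.

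In central memory against naive cells 1739 genes became 4540 with the replicate block, 902 to 2142 without single libraries, 411 with 1 central memory library and 883 at 2-fold or more. Its 166 lncRNAs became 425, 79 to 191 and 46 (block, single libraries, 1 central memory library). In effector memory against naive cells 2046 genes became 4631 with the block, 1363 to 2284 without single libraries and 1228 at 2-fold or more, and 203 lncRNAs became 481, 124 to 243, and 312 without a filter. Between memory populations 17 genes became 144 with DESeq2, 250 without a filter, 35 with only the 2 groups, 428 with the block, 2 to 32 without single libraries, 27 without small and ribosomal RNA genes, 36 with replicate numbers 2 and 3 alone and 0 with 1 central memory library. The 0 lncRNAs there became 10 with DESeq2, 19 without a filter, 1 with only the 2 groups, 28 with the block, 0 to 1 without single libraries and 1 without small and ribosomal RNA genes. The lncRNA share against coding genes there, -0.102 points, was -0.475 with DESeq2, -1.83 with the block and -0.229 to -0.00725 without single libraries.

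Lists called, 18, 23 and 18, became 9, 11 and 8 with an estimated correlation, and fry called 8 between memory populations. Genes shared by both memory populations, 1271, became 3208 with the block, 782 to 1155 without single libraries and 399 with 1 central memory library. Genes in between, 1593, became 3094 with the block. Genes called at both steps in the same direction, 10, became 76 with DESeq2, 220 with the block and 2 to 18 without single libraries. Spearman's correlation of antisense pairs between memory populations, 0.175, ran from 0.0927 to 0.189.

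The sign of CD4, central memory vs naive, log2 fold change 0.07, reversed with upper-quartile scaling (-0.0067), with replicate numbers 2 and 3 alone (-0.0257) and among single libraries left out (-0.0549 to 0.162). That of CD3E, effector memory vs central memory, -0.04, reversed without a filter (0.0086) and without central memory replicate 3 (-0.0952 to 0.0216 over libraries). Named genes past the test or of the sort kept their result in 1327 of 1513 repeats for central memory, 1405 of 1520 for effector memory and 255 of 320 between them. Of 74, 74 and 12 such calls 26, 18 and 10 ended without at least 1 library, and 18, 13 and 6 under another planned setting. For list members that were not past the test the repeats are also given as counts only, a choice made after a first run. The sign of these members reversed in 3 of 140, 5 of 99 and 44 of 519 repeats, and none of those was called. The block ended camera's call of B cell markers in effector memory against naive cells and added that of gamma-delta markers in both comparisons of effector memory cells, which an estimated correlation then ended (adjusted p = 0.0996 and 0.0737). It changed no other list call of the preset test. List member counts were not recounted without single libraries.

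Of 10 splits of each pair's 6 libraries, 1 gave as many genes as observed (0 in the highest other), 1 as many lncRNAs against naive cells, and 10 as many between memory populations, where none was called. For lists 1 did too, but the highest others gave 17, 18 and 15, so camera's list counts carry little weight alone. With 10 splits no share under 0.05 is possible. Of the 9 other splits 3 part all same-number pairs and 6 part only 1, which mixes group with replicate number. These splits, the groupings of all libraries and the simulations of shared controls ignore that pairing.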

Other observations

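The tests in this part were chosen after the result was seen, except the 4 regroupings of libraries in the last paragraph and the bootstrap of divergent pairs, which were set before.

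Cytotoxic genes such as GZMA, CCL5 and NKG7 rose in effector memory cells. NK cells in the sort could bring them, and then TYROBP and FCER1G, abundant in NK cells, should be found with them. Their mean was 0.0699 CPM in effector memory cells, 0.347% of the median of 14 cytotoxic genes, 20.1 CPM, which argues against NK cells as the main source. These 2 genes were picked after levels were seen, replacing a first version with the median of 13 NK markers, which was 0. SPON2, FCGR3A and KLRF1, at 7.81, 2.75 and 2.18 CPM, are shared with cytotoxic T cells and leave some doubt. Gamma-delta T cells were not tested as a source and remain open, since TRGC1 and TRGC2 were at 3.18 and 2.72 CPM in naive and 10.4 and 14.9 CPM in effector memory cells, while TRDC was at 2.66 and 3.28 CPM. In effector memory 1 TRGC2 was at 1.55 CPM, against 26.2 and 16.8 CPM in replicates 2 and 3. GZMA and CCL5 were at 24.0 and 30.8 CPM in effector memory 1. The CD4+ enrichment before the sort would be expected to remove most cells of both kinds, which are largely without CD4.

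The gap between memory populations could also come from naive cells in the central memory sort, which would dilute all memory genes alike. Shares were taken only over list members called higher in effector memory than in naive cells, so other members are left out. Central memory cells showed 10.2% ± 10.7 (SD over 9 genes) of the effector memory excess for cytotoxic genes and 61.7% ± 23.6 (17 genes) for memory surface genes. The difference was -51.5 points (exact permutation over genes, p = 8e-06, 3124550 assignments). That p takes genes as independent and leaves out the spread between libraries, so it describes genes and not donors. With that limit, shares so unlike are not what plain dilution alone would give.

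LncRNAs such as LEF1-AS1 and IFNG-AS1 changed with LEF1 and IFNG. Reads shared by overlapping genes could cause this. Over pairs on opposite strands that do not overlap, Spearman's correlation was 0.394 in effector memory against naive cells (275 pairs). Of 100 groupings of the 9 libraries 4 gave as much, the real one included (highest other 0.412, median 0.168). These pairs include 63 convergent ones, which run toward each other, at 0.597 in that comparison. There a transcript running past its annotated end could still share reads with its partner. Overlap was also judged on an annotation of a later genome build than that of the counting. Shared reads therefore remain open as the source of the joint change. Transcripts running past an annotated end could cause it too and remain open, since divergent pairs gave 0.311 (212 pairs) and 6 of 100 groupings gave as much (highest other 0.366, median 0.154). A bound set before, a bootstrap interval above 0, was met by divergent pairs (0.170 to 0.438), but it was the wrong bound, as other groupings do not give 0 either. Over the 275 pairs the correlation was 0.230 in central memory against naive cells and 0.126 in effector against central memory cells. Divergent pairs gave 0.201 and 0.126 there, the last with a bootstrap interval of -0.0165 to 0.262. No groupings were made for these comparisons, and both explanations remain open in them too.

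Of 100 groupings of the 9 libraries, 1 gave a Spearman's correlation as high as the 0.516 observed for pairs by name (highest other 0.512), but all 99 others were above 0, with a median of 0.247. Other groupings can still hold part of the difference between naive and memory libraries, so their median is not a value free of it. They also include the real 3 groups under exchanged names, and some groupings with identical correlations. For the correlations the 99 are therefore not all distinct, which limits the counts out of 100 here and above. How much of the coupling is variation between libraries of any kind remains open. As many genes shared by both memory populations as the 1271 observed came from 2 groupings (highest other 1279), as many in between as 1593 from 2 (highest other 3019), and as many called at both steps as 10 from 1 (highest other 0). Of the 99 others 6 keep the naive libraries together, and without those the highest were 44 shared, 343 in between and a Spearman's correlation of 0.436.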
